A study of Rattus norvegicus with 6 samples.

How the data were processed

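AR42J cultures, 3 control and 3 with dexamethasone, were profiled on 6 Affymetrix Rat 230A arrays, 1 per culture. Per the labels' protocols, the experiment was done 3 times over 5 months, each time with cells thawed at passage 29. Cells were plated for 24 h in medium with 20% serum and then kept for 48 h in medium with 5% serum with or without 100 nM dexamethasone. Total RNA was extracted with Trizol and labelled with biotin. The series' design text calls the cultures independent pairs of a control and a treated culture. With replicate number as a block, the p-values cover the spread of the treated minus control difference over replicate numbers. They apply to 1 cell line at 1 dose and 1 time.

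The deposited values are 1 intensity per probe set and array, the MAS5 signal on a linear scale made with GCOS and MAS5 per the submitters' processing notes. Software versions, scaling settings and any probe masks were not given in the sources used here, and detection calls and scans of the arrays were not used here. Checked on the values, each array had a mean signal of about 500 after the top and bottom 2% were trimmed, so signals are relative to the array's own total and a change in RNA content per cell would not be seen. MAS5 subtracts a local background and mismatch signal, which makes low signals noisy, and very bright probe sets can saturate. Replicates were not pooled. No pair of arrays had more than 47 identical values among 15866 probe sets, so no array's values were held under more than 1 sample.

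The table held 15923 probe sets, of which 57 were array controls and 15866 entered the analysis. Probe sets were named from the GEO platform annotation with symbols updated through the NCBI gene table of the rat assembly GRCr8: 12783 had 1 gene symbol, 312 had several and were given no name, and 2771 were unnamed here. Counted over all one-symbol entries of the platform annotation, not only the probe sets analysed, 12754 matched by gene identifier and 2 by accession. Of these entries, 33 kept the platform's symbol, and 1 symbol was updated. Coordinates were not used. A gene was represented by its one-symbol probe set with the highest mean log2 signal over the 6 arrays, which gave 10411 genes. Among second probe sets that changed along with a changed gene, 234 in number, 7 went the opposite way. Probe sets whose identifiers end in _a_at, _s_at or _x_at, and those of gene families, can measure more than 1 transcript.

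Signals were taken to log2 after 4 values of 0 were set to 0.1. Probe sets entered the test if their mean log2 signal over the 6 arrays reached the 40th percentile of non-control probe sets (a signal of 147.6), which left 9520 probe sets and 7051 genes. A linear model with treatment and replicate number as a block was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Arrays were not normalized again. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

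A background level per array was set as the highest signal of 27 control probe sets for Bacillus subtilis genes, a choice made after the data were examined. Where a probe set was below it on every array of a group, the change was given as a bound, the mean log2 of the brighter group against the mean of the higher of the background level and the probe set's own signal per array. Among changed probe sets, 2 were at background in all control arrays and 13 in all treated arrays. The level itself was 54.5, 97.3 and 51.7 in controls 1 to 3 and 100.2, 83.7 and 115.9 in dexamethasone 1 to 3. It thus tended to be higher in treated arrays, where a signal of the same size is more easily counted as at background.

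Tests of 16 gene lists used camera on 1 probe set per gene, with a preset correlation of 0.01 and adjustment over the lists. The lists, with at least 5 measured members each, covered digestive enzymes and zymogen granule cargo, acinar transcription factors, exocytosis and granule membrane machinery, endoplasmic reticulum protein processing, the integrated stress response and amino acid synthesis, glucocorticoid-responsive genes, cell cycle and DNA replication, cholesterol and fatty acid synthesis, islet and neuroendocrine genes, duct cell genes, hepatocyte genes, secretagogue receptors and calcium signalling, pancreatitis and acinar stress genes, stromal, endothelial and immune markers, ribosomal proteins, and mitochondrial oxidative phosphorylation. They were drawn from general knowledge and not from these samples. Of 644 list entries, 530 were on the array under a single symbol. Camera compares a list with all other genes; fry, run as an alternative, asks whether the genes of a list move one way.

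Named genes were the 10 largest rises and 10 largest falls among genes past the threshold that moved the same way in all 3 pairs and whose brighter group reached the median signal of the array, up to 4 changed members with the largest change in each list with a call or at least 3 changed members, and 24 genes fixed beforehand whatever their result, of which 23 were on the array. Other genes are named as chosen after their values were seen.

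Alternatives were a fit without the replicate block, quantile normalization, centring on the median or 75th percentile, no filter or a 60th percentile filter, a floor or a pseudocount at the 20th percentile of signals (53.1), no intensity trend, the mean of a gene's probe sets, changes of at least 1.5-fold or 2-fold, leaving out each pair, fry, and camera with an estimated correlation. Added after the data were examined were scaling to 18 hybridization control probe sets (bioB, bioC, bioD and cre), leaving out each single array without the block, and camera with an estimated correlation without the block. RNA integrity was compared within pairs by an exact sign-flip permutation test, whose smallest two-sided p with 3 pairs is 0.25. The test was checked on simulated data for the same comparison and 9520 probe sets, 200 of them changed. It recovered 15.5% of 1.5-fold, 70.8% of 2-fold and 100% of 4-fold changes, with 6 false calls. With so few changed, adjustment is stricter than in the data, where 3531 were called, so these shares do not carry over to the data. In simulated lists over 7051 genes, camera with the preset correlation called a list of 15 genes shifted by 1 on the log2 scale. With an estimated correlation it did not (adjusted p = 0.0771). The simulated genes varied independently, so a preset near 0 was right by construction. In the data the estimated correlation ran from -0.06 (duct cell genes) to 0.49 (digestive enzymes), with 0.47 for ribosomal proteins. The simulation therefore cannot show which version holds for the data. For glucocorticoid-responsive (-0.02) and hepatocyte genes (0.0076) the estimate was below the preset 0.01. Correlation between genes cannot be why these lists lost their calls with the estimated version. That version also missed the shifted list among independent genes, so a call lost with it is weak evidence against a list. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.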

Results

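Messenger RNA levels were measured in AR42J, a rat cell line derived from an exocrine (acinar) tumour of the pancreas, after 48 h with or without dexamethasone. Dexamethasone is a synthetic glucocorticoid that acts through the glucocorticoid receptor, and AR42J cells are widely used as a model of acinar cells that respond to it. Cultures at passage 29 received medium alone (control, n = 3) or medium with 100 nM dexamethasone (n = 3), and total RNA from each culture was hybridised to an Affymetrix Rat 230A array. The comparison asks how dexamethasone changed gene expression in these cells. Each array had a trimmed mean signal of about 500, and 68.3% to 79.5% of probe sets per array lay above that array's background level, which ranged from 51.7 to 115.9. Values below are mean signal ± SD over the 3 cultures of a group, log2 changes are dexamethasone minus control with their SE from limma, and adjusted p-values are limma's with Benjamini-Hochberg adjustment. The number of arrays (3 per group) limits the precision.

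With dexamethasone, 22 of 26 measured glucocorticoid-responsive genes rose and 31 of 33 measured cell cycle and DNA replication genes fell. Hpd, which encodes an enzyme of tyrosine breakdown, had the largest fitted rise, from 73.4 ± 18.0 to 7078 ± 2384 (log2 change 6.57 ± 0.18, adjusted p = 1.7e-07). However, 1 of its 3 control arrays was not above background, and rises from background, such as that of Tat below, cannot be ranked exactly. Sgk1, a kinase gene induced by glucocorticoids, rose from 113.9 ± 8.43 to 7333 ± 2455 (5.96 ± 0.17, adjusted p = 1.9e-07). Mcm6, a subunit of the replicative helicase, fell from 2352 ± 316 to 83.0 ± 23.2 (-4.85 ± 0.17, adjusted p = 5.1e-07), and Cdk1, the kinase that drives entry into mitosis, fell from 1643 ± 105 to 83.8 ± 30.1 (-4.35 ± 0.23, adjusted p = 2.8e-06). Of the 3 treated arrays, 1 was above background for Mcm6 and 1 for Cdk1.

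Across the array, 3531 of 9520 probe sets tested (37.1%) passed an adjusted p of 0.05 by limma, 1512 higher and 2019 lower with dexamethasone. Of these, 3519 moved the same way in all 3 replicate pairs. They were selected by a fit on the same pairs, which favours such agreement, so it is no separate evidence. A change of at least 2-fold was seen in 478 higher and 629 lower probe sets. Taking 1 probe set per gene, 2705 of 7051 genes changed, 1196 higher and 1509 lower. The balance of directions depended on how arrays were scaled: 42.8% of changed probe sets were higher with the deposited scaling, 57.5% (2037 higher, 1503 lower) when arrays were centred on their 75th percentile, and 19.3% (778 higher, 3257 lower) when they were scaled to the hybridization controls. The median log2 change of all probe sets tested was -0.05, 0.08 and -0.29 in these settings, and 42.8% therefore describes the deposited scaling alone. Centring and hybridization control scaling shift all genes of an array alike and so cannot change a list's median relative to that of all genes. Quantile normalization can, and took it from 0.34 to 0.0045 for ribosomal proteins and from 0.27 to 0.059 for endoplasmic reticulum genes. Arrays correlated more closely within the control group (Pearson r over probe sets 0.971 to 0.983) and within the dexamethasone group (0.956 to 0.969) than between groups (0.835 to 0.856), and the first principal component, with 76.0% of the variance, separated the groups. On the second component (10.0%) dexamethasone 3 stood apart, at 25.3 against -11.6 and -12.6 for the other treated arrays. These correlations run over probe sets, which are not independent replicates.

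Besides Hpd and Sgk1, the 10 largest rises included Tat (tyrosine aminotransferase, a liver enzyme induced by glucocorticoids), which was not above background on any control array (23.5 ± 10.4) and reached 1367 ± 557 with dexamethasone, at least 20.0-fold higher (adjusted p = 1.2e-06). Sult1a1, a phenol sulfotransferase, rose from 266.8 ± 57.1 to 13568 ± 2575 (5.67 ± 0.14, adjusted p = 1.5e-07). Stap2, Kcnip3, Cdc42ep2 and Prss3b rose by 4.30 to 5.00 on the log2 scale, with 1 of 3 control arrays above background for each. C3, the central complement component, rose by 4.64 ± 0.62, with 2 of 3 control arrays above background and treated signals of 1681, 3123 and 294.9. Its change was 3.59 without replicate 2 and 5.74 without replicate 3. Prss1, a trypsinogen gene, rose from 726.1 ± 98.9 to 15481 ± 361 (4.42 ± 0.11, adjusted p = 1.5e-07). Prss1 and Prss3b belong to a family of near-identical trypsinogens, so the share of each family member in these signals is uncertain. The change of Prss3b was 3.48 without replicate 2 and 4.96 without replicate 3, and that of Kcnip3 was 3.87 without replicate 3. Adding a pseudocount of 53.1 to the signals moved 15 of the 79 named genes by over 1.5-fold without ending a call, among them Hpd (5.78), Stap2 (3.91) and Cks2 (-3.91), and understates the change of dim genes.

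The 10 largest falls were in Cks2, Mcm6, Spc25, Dnmt1, Cdk1, Pclaf, Spc24, Top2a, Agtr2 and Mki67. Spc25 and Dnmt1 were not above background on any treated array. Spc25, a kinetochore component, fell from 1234 ± 73 to that level, at least 12.4-fold (adjusted p = 2.0e-06), and Dnmt1, the maintenance DNA methyltransferase, fell from 968.8 ± 58.5, at least 9.77-fold (adjusted p = 8.8e-06). Pclaf, which binds the replication clamp, fell from 2405 ± 184 to 120.9 ± 5.5 and was above background on all 6 arrays (-4.31 ± 0.14, adjusted p = 3.5e-07). Agtr2, the type 2 angiotensin receptor, fell from 2007 ± 238 to 110.6 ± 6.7 (-4.18 ± 0.15, adjusted p = 5.1e-07) with 2 treated arrays above background, and its other probe set fell by 3.22. Cks2 (-4.95) and Spc24 (-4.27) each had 1 treated array above background, and without replicate 1 their changes were -4.32 and -3.56, while that of Spc24 was -4.96 without replicate 2.

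Of 26 measured genes on a list of glucocorticoid-responsive genes, 22 rose, 2 fell and 2 did not pass the threshold. Adjusted over the list alone, 22 rose and 3 fell. Fkbp5, a co-chaperone of steroid receptors and a standard marker of receptor activity, rose from 455.0 ± 7.9 to 2958 ± 397 (2.69 ± 0.13, adjusted p = 2.3e-06). Cebpb, a transcription factor, rose by 3.84 ± 0.17, and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, by 1.68 ± 0.17. Per1, a clock gene, rose by 2.38 ± 0.33 with 2 of 3 control arrays above background, and by 1.65 without control replicate 2. The receptor gene itself, Nr3c1, fell by 0.48 ± 0.13 (adjusted p = 0.0157), a call lost when arrays were centred on their 75th percentile (adjusted p = 0.0513) and without replicate 1 or 3, and its other probe set did not pass (-0.47 ± 0.25, adjusted p = 0.175). The list median was 2.28, and camera, with a preset correlation between genes, called the list higher (adjusted p = 4.4e-15, against adjusted p = 0.151 with an estimated correlation).

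Cell cycle and DNA replication genes moved the other way: of 33 measured, 31 fell, 1 rose and 1 did not pass. Adjusted over the list alone, 31 fell and 2 rose. Top2a, the DNA topoisomerase of dividing cells, fell from 2662 ± 164 to 151.1 ± 45.0 (-4.18 ± 0.16), and Mki67, the gene of the Ki-67 proliferation marker, from 1361 ± 244 to 95.9 ± 45.1 (-3.92 ± 0.26). Of the 3 treated arrays, 2 were above background for Top2a and 1 for Mki67. The riser was Myc, a transcription factor of growing cells, at 0.65 ± 0.13, and the gene that did not pass was Ccnd3 (0.36 ± 0.13), both named after their values were seen. The median was -2.30 (camera adjusted p = 2.1e-18; adjusted p = 0.151 with an estimated correlation).

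**Figure D1:**
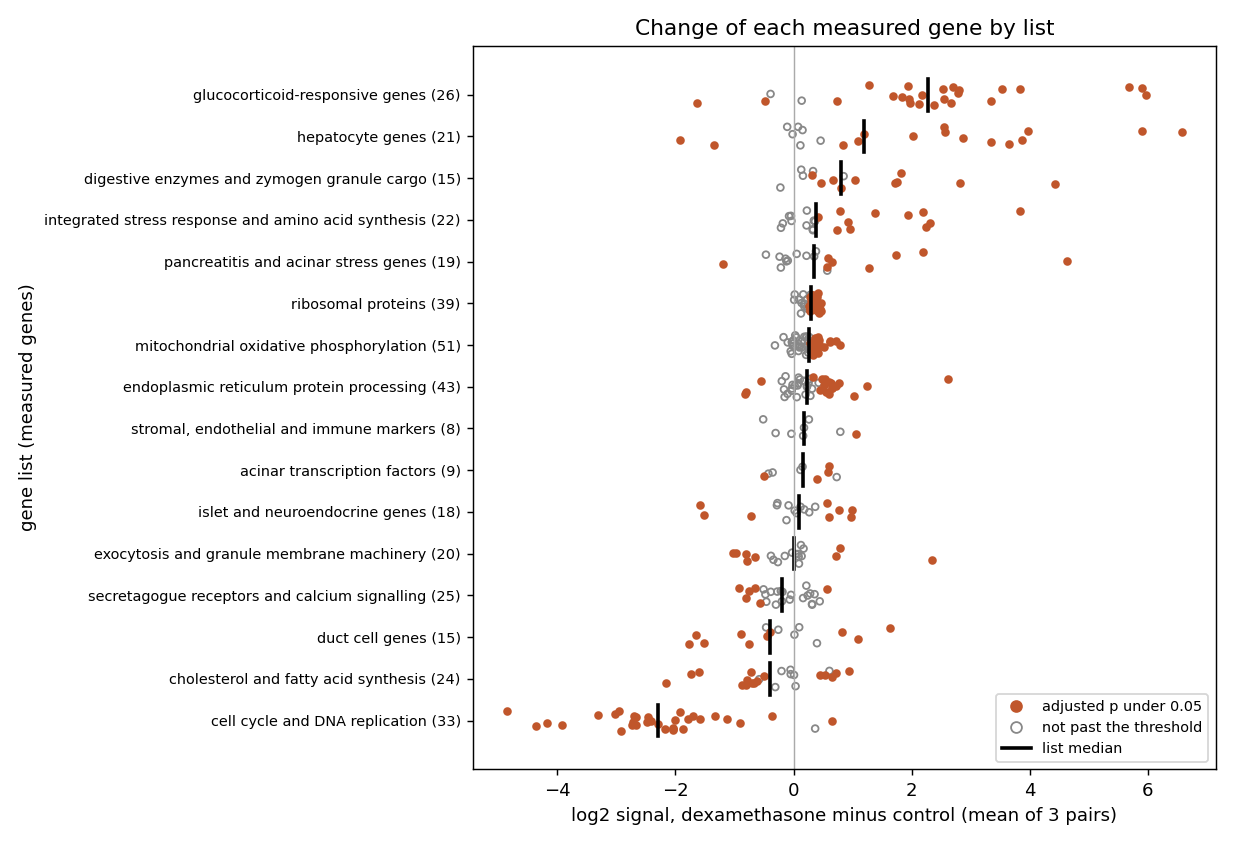
Log2 change in MAS5 signal (x axis, dexamethasone minus control, mean of 3 pairs) of every measured gene in each of 16 gene lists (y axis, measured genes in parentheses). Filled points passed limma's adjusted p of 0.05 and open points did not. Black bars mark list medians, which run from 2.28 for glucocorticoid-responsive genes to -2.30 for cell cycle genes. Small medians depended on the scaling. The 0.30 of ribosomal proteins was 0.019 with quantile normalization and 0.42 with 75th percentile centring. The 0.23 of endoplasmic reticulum genes was -0.02 with scaling to the hybridization controls and 0.35 with 75th percentile centring.

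Digestive enzymes and other zymogen granule cargo, the secreted products of acinar cells, ranged widely in control cultures: 5 of 15 measured had signals above 10000, and another 8 on the array were too dim to test. Of the 15, limma called 10 higher and 0 lower, with the same counts adjusted over the list alone and at an unadjusted p under 0.05, and 5 did not pass. With quantile normalization 8 rose and 2 fell, and with scaling to the hybridization controls 9 rose and 1 fell. Apart from Prss1, the largest rises were in Ctrc (a chymotrypsin, 2874 ± 765 to 19874 ± 198, 2.82 ± 0.14), Cela2a (an elastase, 4450 ± 732 to 15484 ± 694, 1.81 ± 0.10) and Sycn (syncollin, a zymogen granule membrane protein, 1.76 ± 0.12). The treated signals of Prss1, Ctrc and Cela2a, like those of Sult1a1 and Ass1, lay above 10000, where a signal ceiling was not excluded, and with a ceiling these rises would be lower bounds. Amy2a3, pancreatic amylase, went from 14647 ± 1361 to 18226 ± 759 (0.32 ± 0.09, adjusted p = 0.0274), a call lost with quantile normalization (0.01, adjusted p = 0.949), with hybridization control scaling, with no filter, with no intensity trend, and without replicate 1 or replicate 3. Ctrb1, chymotrypsinogen B, rose by 0.46 ± 0.09 (adjusted p = 0.00434), a call also lost with quantile normalization (0.10, adjusted p = 0.198). Cpa1, carboxypeptidase A1, did not differ beyond the replicate spread (-0.22 ± 0.10, adjusted p = 0.108), but was past the threshold and lower with quantile normalization (-0.51, adjusted p = 0.00361) and hybridization control scaling (-0.47). The list median was 0.80 (camera adjusted p = 2.5e-06; adjusted p = 0.540 with an estimated correlation), 0.53 without replicate 1 and 1.20 without dexamethasone replicate 3 in a fit without pairs. Amylase genes also form a near-identical family, and probe sets of such families may be shared.

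Of 9 measured transcription factors of acinar cells, 3 rose, 1 fell and 5 did not pass, or 3 and 2 adjusted over the list alone. With hybridization control scaling the balance turned, with 1 higher and 3 lower. Ptf1a, which specifies acinar fate, rose from 2616 ± 195 to 3985 ± 360 (0.61 ± 0.11, adjusted p = 0.00229), and Bhlha15 (Mist1), required for secretory cell architecture, rose by 0.59 ± 0.16 (adjusted p = 0.0226). Xbp1 rose by 0.40 ± 0.10 and Gata4 fell by 0.50 ± 0.16, while the other probe set of Gata4 did not pass (-0.45 ± 0.17, adjusted p = 0.0644). The call of Gata4 was lost with quantile normalization, both centrings, no filter, no intensity trend and without replicate 2, that of Xbp1 with quantile normalization, hybridization control scaling, no intensity trend and without replicate 3, and that of Bhlha15 with hybridization control scaling and without replicate 1. The median was 0.15 (-0.10 with hybridization control scaling, 0.26 without replicate 1 and 0.30 without replicate 3), with a camera adjusted p of 0.450. The probe set of Pdx1, a pancreatic progenitor factor, was too dim to be tested (16.6 ± 7.6 and 20.6 ± 8.5).

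Among 43 measured genes of protein processing in the endoplasmic reticulum, 16 rose, 3 fell and 24 did not pass, or 17 and 3 adjusted over the list alone. The counts were 8 higher and 6 lower with hybridization control scaling and 23 higher and 3 lower with 75th percentile centring. Herpud1, induced when unfolded protein accumulates, rose from 439.1 ± 62.0 to 2689 ± 178 (2.62 ± 0.13, adjusted p = 2.1e-06). Ero1b, an oxidase of disulfide formation, rose by 1.25 ± 0.17 and Sec11c, a subunit of the signal peptidase, by 1.02 ± 0.12, whereas Pdia4, a disulfide isomerase, fell by 0.83 ± 0.15. The median of 0.23 became -0.02 with hybridization control scaling, where camera still called the list higher relative to other genes (adjusted p = 0.00643). The camera call (adjusted p = 0.000594) was lost with quantile normalization (adjusted p = 0.113) and with an estimated correlation (adjusted p = 0.540).

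Of 20 measured genes of exocytosis and the granule membrane, 3 rose, 5 fell and 12 did not pass, with the same counts adjusted over the list alone, and 2 rose and 7 fell with hybridization control scaling. Anxa2, a calcium-dependent membrane-binding protein, rose from 259.8 ± 52.1 to 1330 ± 341 (2.34 ± 0.14, adjusted p = 5.3e-06). Stx4, a syntaxin of the plasma membrane, fell by 1.03 ± 0.16, Syt7, a calcium sensor of exocytosis, by 0.98 ± 0.21, and Cadps, a priming factor, by 0.81 ± 0.12. Rab3d, a zymogen granule GTPase, did not pass (-0.34 ± 0.16, adjusted p = 0.117), but was past the threshold and lower with hybridization control scaling and without replicate 1. The list median was 0.01 (-0.07 without replicate 1 and -0.06 without replicate 3) and its mean -0.04, with camera's direction down and fry's up, and camera made no call (adjusted p = 0.739).

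Secretagogue receptors and calcium signalling genes showed 1 riser, 5 fallers and 19 that did not pass among 25 measured (1 and 4 adjusted over the list alone). With hybridization control scaling limma called 11 lower and 0 higher, and with 75th percentile centring 5 higher and 4 lower. Plcb1, a phospholipase that couples receptors to calcium release, fell by 0.93 ± 0.18, Atp2c1, a Golgi calcium pump, by 0.81 ± 0.17, and Sstr2, a somatostatin receptor, by 0.75 ± 0.17, with its other probe set falling by 1.91. Camk2g fell by 0.66 ± 0.21 (adjusted p = 0.0366), a call lost without any 1 of the 3 replicate pairs, with 75th percentile centring and with no filter. Cckbr, the gastrin and cholecystokinin receptor, did not pass (0.31 ± 0.13, adjusted p = 0.0856), but was past the threshold and higher with quantile normalization and 75th percentile centring, and its other, dimmer probe set passed (0.45 ± 0.15, adjusted p = 0.0471). Cckar was not analysed here. The list median was -0.20 (-0.07 without dexamethasone replicate 2 in a fit without pairs) and camera made no call (adjusted p = 0.512).

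**Figure D2:**
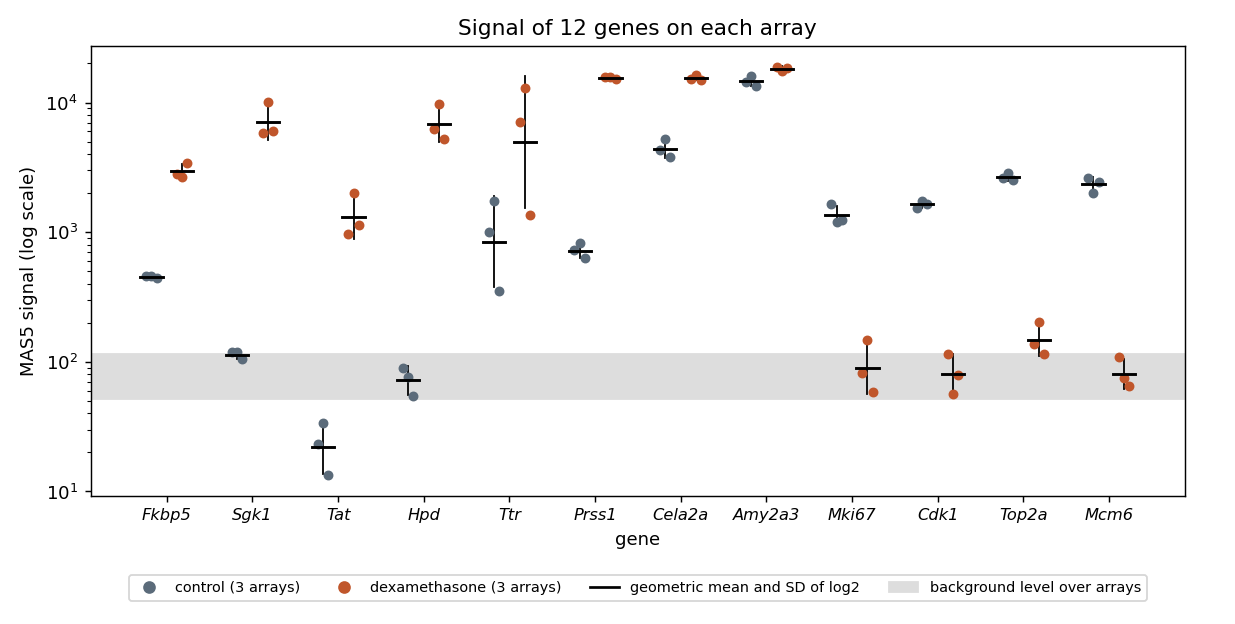
MAS5 signal on each array (y axis, log scale) of 12 genes (x axis), with 3 control and 3 dexamethasone arrays each; bars give the geometric mean and the SD of log2 signal, and the grey band spans the background levels of the arrays (51.7 to 115.9). As arithmetic means, Hpd and Sgk1 rose from 73.4 and 113.9, inside the band, to 7078 and 7333. Each array has its own level within the band, and Sgk1 was above that level on all 3 control arrays. Cdk1 and Mcm6 fell into the band (83.8 and 83.0), and Amy2a3 lay above 10000 in both groups. Ttr, chosen after its values were seen, had treated signals from 1348 to 12962.

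A list of hepatocyte genes, included as markers of another cell type, had 13 risers, 2 fallers and 6 genes that did not pass among 21 measured, with the same counts adjusted over the list alone, and another 21 were too dim to test. Besides Hpd and Tat, Ass1, an enzyme of the urea cycle that makes argininosuccinate, rose from 1178 ± 371 to 17769 ± 1636 (3.96 ± 0.17, adjusted p = 1.4e-06), and Apoa1, the main protein of high-density lipoprotein, from 201.2 ± 95.3 to 3441 ± 2545 (3.87 ± 0.24). Apoa1 ranged from 1100 to 6149 among treated arrays, and its change was 4.53 without dexamethasone replicate 3. Hnf4a, a liver-enriched transcription factor, rose by 0.84 ± 0.16 (adjusted p = 0.00388). Alb, the albumin gene, was too dim to be tested (96.1 ± 18.4 and 109.1 ± 40.5). The fallers, Igfbp2 (-1.93 ± 0.13), which binds insulin-like growth factors, and Ambp (-1.35 ± 0.18), were named after their values were seen. The median was 1.20 (camera adjusted p = 8.9e-07; adjusted p = 0.181 with an estimated correlation). It depended on which members were bright enough to enter, at 0.75 with no filter and 2.55 with the stricter filter, with camera's call held in both, and 2 of the 21 measured genes were also on the glucocorticoid-responsive list.

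Of 22 measured genes of the integrated stress response and amino acid synthesis, limma called 11 higher and 0 lower, with the same counts adjusted over the list alone, and 11 did not pass. At an unadjusted p under 0.05, 13 were higher and 0 lower, and with hybridization control scaling 10 were higher and 1 lower. Besides Cebpb, the largest rises were in Slc7a5 (2.31 ± 0.15) and Slc3a2 (2.25 ± 0.10), the light and heavy chains of an amino acid transporter, and in the stress-induced nuclear protein gene Nupr1, from 1582 ± 246 to 7221 ± 1092 (2.19 ± 0.15). The median was 0.38 (camera adjusted p = 3.7e-06; adjusted p = 0.337 with an estimated correlation).

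Cholesterol and fatty acid synthesis genes went both ways: of 24 measured, 5 rose, 11 fell and 8 did not pass, or 6 and 11 adjusted over the list alone. With hybridization control scaling 1 rose and 13 fell. Sqle, squalene epoxidase, fell from 498.5 ± 52.1 to 118.5 ± 53.9 with 1 treated array above background (-2.16 ± 0.23, adjusted p = 0.000155). Fads1, a fatty acid desaturase, fell by 1.74 ± 0.18 and Dhcr7, a late enzyme of cholesterol synthesis, by 1.61 ± 0.27, while Thrsp, a lipogenic protein, rose by 0.94 ± 0.24, a call lost without replicate 1 or 3. The median was -0.41 and camera made no call (adjusted p = 0.101), but the list was called lower with no intensity filter (adjusted p = 0.0171) and without replicate 2 (adjusted p = 0.0338).

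Ribosomal protein genes, among the brightest on the array, had a small positive median. Of 39 measured, limma called 25 higher and 0 lower, and 14 did not pass. Adjusted over the list alone, and at an unadjusted p under 0.05, 30 were higher and 0 lower. Rpl4 rose by 0.47 ± 0.13, Rpl23 by 0.46 ± 0.11, Rpl37a by 0.45 ± 0.10 and Rpl21 by 0.42 ± 0.09. All 4 calls were lost with no intensity trend, those of Rpl4, Rpl23 and Rpl37a without replicate 1, those of Rpl4, Rpl23 and Rpl21 with hybridization control scaling, and that of Rpl4 also with no filter. With quantile normalization none of these 4 passed and 1 gene of the list did, lower (median 0.019 in place of 0.30). With hybridization control scaling 1 was higher (median 0.054). The centrings went the other way, with 31 higher on the median (0.37) and 33 higher on the 75th percentile (0.42), and 0 lower in both. Camera's call (adjusted p = 3.5e-07) was lost with quantile normalization (adjusted p = 0.834) and with an estimated correlation (adjusted p = 0.558).

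Mitochondrial oxidative phosphorylation genes also had a small positive median, with 20 of 51 measured higher, 0 lower by limma and 31 not past the threshold. Adjusted over the list alone, 21 were higher and 0 lower, and at an unadjusted p under 0.05, 26 were higher and 1 lower. Ndufs7 (0.78 ± 0.15) and Ndufa2 (0.71 ± 0.11), subunits of complex I, and Sdha (0.62 ± 0.11) and Sdhb (0.62 ± 0.14), subunits of complex II, had the largest rises, and the call of Sdhb was lost with hybridization control scaling and without replicate 2. The median of 0.26 was 0.11 with quantile normalization (6 higher, 3 lower) and 0.012 with hybridization control scaling (3 higher, 3 lower). It was 0.33 with median centring (25 higher, 0 lower) and 0.38 with 75th percentile centring (32 higher, 0 lower). Camera called the list higher (adjusted p = 2.3e-05), a call lost with quantile normalization (adjusted p = 0.122) and with an estimated correlation (adjusted p = 0.638).

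AR42J cells also carry neuroendocrine features. Of 18 measured islet and neuroendocrine genes, 5 rose, 3 fell and 10 did not pass, with the same counts adjusted over the list alone. With hybridization control scaling 3 rose and 5 fell. Ddc, the decarboxylase of monoamine synthesis, fell from 3048 ± 145 to 1040 ± 300 (-1.59 ± 0.16), although its other, dimmer probe set did not pass (-0.20 ± 0.26), and Uchl1, a neuronal hydrolase, fell by 1.52 ± 0.12. Th, tyrosine hydroxylase, rose by 0.99 ± 0.28 with 2 of 3 control arrays above background, a call lost with hybridization control scaling, with no filter and without replicate 1 or 2, and Gad2, a glutamate decarboxylase, rose by 0.98 ± 0.22. Ins1 (0.05 ± 0.22) and Cck (0.18 ± 0.24) did not pass, and Ins2 and Sst were too dim to test. Ins1 and Ins2 are close paralogs whose signals may be shared. The median was 0.08 (-0.16 with hybridization control scaling, 0.17 without replicate 2 and -0.07 without replicate 3), camera's direction was up and fry's down, and camera made no call (adjusted p = 0.663).

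Of 15 measured duct cell genes, 3 rose, 7 fell and 5 did not pass, with the same counts adjusted over the list alone. Onecut1, a transcription factor of duct development, fell from 892.1 ± 123.3 to 260.7 ± 20.1 (-1.77 ± 0.16), and its other probe set fell by 1.34. Krt19, a duct keratin, fell by 1.66 ± 0.32 (adjusted p = 0.00371), with treated signals of 1388, 1423 and 316.2, and its change was -1.05 without replicate 3 and -0.94 without dexamethasone replicate 3 in a fit without pairs. In that kind of fit its call was lost without control replicate 1 (adjusted p = 0.0543) or control replicate 2 (adjusted p = 0.0735). Tff2, a trefoil peptide, fell by 1.52 ± 0.19, and Hes1, a Notch target, rose by 1.63 ± 0.15. The median was -0.40 (-0.19 without replicate 1) and camera made no call (adjusted p = 0.464).

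Pancreatitis and acinar stress genes had 7 risers, 1 faller and 11 that did not pass among 19 measured, or 7 and 2 adjusted over the list alone, and 4 rose and 2 fell with hybridization control scaling. After C3 and Nupr1, the largest rises were in Clu, a secreted chaperone, at 1.73 ± 0.14, and Lcn2, an iron-carrier-binding acute phase protein, at 1.27 ± 0.30, a call lost without replicate 1 or 2. The faller was Reg3b (-1.19 ± 0.24), a lectin induced in pancreatitis, named after its value was seen, and Reg genes are a family of close paralogs. The median was 0.35, and the camera call (adjusted p = 0.04996) was lost under quantile normalization and both centrings, with no filter or a stricter filter, with a pseudocount, without replicate 1, and with an estimated correlation (adjusted p = 0.540).

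Of stromal, endothelial and immune markers, 26 were too dim to test and 8 were measured. Pecam1, an endothelial adhesion molecule, rose by 1.05 ± 0.27 (120.7 ± 21.5 to 254.6 ± 68.6), and 7 did not pass. Limma called 0 lower, with the same counts adjusted over the list alone, and at an unadjusted p under 0.05, 2 were higher and 1 lower. With hybridization control scaling 1 was higher and 2 lower. Pecam1 was named after its value was seen. The median was 0.17 (-0.08 with hybridization control scaling, 0.0089 without replicate 1 and 0.34 without replicate 2) and camera made no call (adjusted p = 0.512).

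RNA integrity, read from the ratio of 3' to 5' probe sets, did not differ beyond the spread between pairs for Actb (log2 difference 0.09 ± 0.27 SD, n = 3 pairs, exact two-sided permutation p = 1) or Gapdh (-0.0041 ± 0.092, exact permutation p = 1). Dexamethasone 3 had the highest ratio for Actb of the 6 arrays (1.69, against 1.46 and 1.19 in the other treated arrays) and the lowest for Gapdh (0.973). The ratio of 3' to middle probe sets was lower with dexamethasone in all 3 pairs for Actb (-0.23 ± 0.13) and higher in all 3 for Gapdh (0.10 ± 0.04), each with an exact permutation p of 0.25, the smallest that 3 pairs allow. Of the 16 lists, camera called 8 higher and 1 lower with the preset correlation. With an estimated correlation it called 0, with 3 at an unadjusted p under 0.05, while fry called 5. Some genes stand on 2 lists, among them Tat and Pck1 (glucocorticoid-responsive and hepatocyte), Cebpb (glucocorticoid-responsive and stress response), Nupr1 (stress response and pancreatitis) and Lcn2 (glucocorticoid-responsive and pancreatitis).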

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

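The tests of liver cells, of genes shared between lists, of a signal ceiling and of hybridization control scaling were chosen only after the results were seen, and the liver cell test, first run in another form, and the reading of the brightness test for ribosomal proteins were changed then.

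The control probe set AFFX-LysX-M_at, for a Bacillus subtilis gene outside the comparison, had a mean signal of 16.2 with dexamethasone against 6.63 in control cultures (limma adjusted p = 0.0423 over 57 control probe sets). A further probe set for the same gene, AFFX-r2-Bs-lys-M_at, had a mean signal of 28.2 against 2.87 (limma adjusted p = 0.0423), while the other 4 probe sets for this gene did not pass. Both belong to the 27 that give the background level, and their mean signals lay below its range of 51.7 to 115.9.

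Ribosomal protein genes (median log2 change 0.30) and oxidative phosphorylation genes (0.26) had small positive medians, with 14 of 39 and 31 of 51 genes not past the threshold. A general upward trend of bright probe sets is a candidate explanation. Of 10000 random lists matched on mean level, 5.07% had a median as high as that of the oxidative phosphorylation genes. At the limit of 2.5% set beforehand, these genes were not set apart from that trend. The typical matched list rose less, by 0.10 against 0.26, so the test does not show that the trend accounts for the whole rise. For ribosomal proteins the typical matched list rose by 0.17 against 0.30, and 0.99% of matched lists rose as much. That met the bound set beforehand for arguing against the trend. The bound was judged inadequate once the result was seen, because the matched lists were dimmer (mean log2 signal 13.27 against 13.59) and quantile normalization took the list median to 0.019. Scaling to the hybridization controls lowers all genes alike, so it took the medians to 0.054 and 0.012 but left them 0.34 and 0.30 above the median of all genes, with both lists still called by camera (adjusted p = 0.000299 and 0.00643, against 0.834 and 0.122 with quantile normalization and 0.558 and 0.638 with an estimated correlation), and a scaling of that kind therefore bears on the absolute rise and not on the rise relative to other genes. The absolute rise cannot be told apart from array scaling, because nothing here measures RNA per cell independently. Nor can the relative rise of either list be told apart from the trend with brightness.

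Part of the hepatocyte list was higher with dexamethasone, led by Hpd, Tat and Ass1. Liver cells in the treated cultures would bring all abundant liver transcripts, but the log2 change of albumin was 0.13 ± 0.37 (SE), Ambp fell by 1.35, and of 15 abundant hepatocyte secretory transcripts tested with no filter 7 were higher, 1 lower and 7 not past the threshold, which argues against them as the whole source. This rests on Ambp (841.6 to 312.8), Apob (0.11 ± 0.21) and the dim Ahsg (154.5 to 152.1, -0.02 ± 0.23). Alb, Apoa2, Fga, Fgb and Fgg lay at or near background in both groups, and Rbp4 (8.20 to 53.4) is counted as higher at that level. In addition, 7 of 15 was close to the bound, set after the values were seen, of fewer than 8. Nor did the pattern rest on the 2 members shared with the glucocorticoid-responsive list, since camera with its preset correlation called the other 19 (p = 7.9e-06, adjusted p = 2.1e-05 over 16 lists, median 1.08, 11 higher and 2 lower). A rise of part of a hepatocyte program in AR42J cells stays open as a hypothesis. It was found and tested on the same data, and other technical explanations were not tested. The camera call of the whole list was lost with an estimated correlation (adjusted p = 0.181), but that estimate (0.0076) was below the preset 0.01. Correlation between its genes therefore did not end the call, and nothing is concluded from its loss.

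Among digestive enzymes, the 5 genes with control signals above 10000 (such as Cpa1, Amy2a3 and Ctrb1) changed by -0.22 to 0.46 on the log2 scale, against a median of 1.38 for the other 10. A signal ceiling is a candidate explanation: the largest log2 rise among 62 named probe sets above 10000 in control arrays was 0.46, whereas 82 of 2082 (3.94%) between 1000 and 10000 rose at least 2-fold. A limit common to all probe sets would have left Cela1 room (10540 to 11594, while Ctrc reached 19874), but single probes can saturate at different signals, and probe sets above 10000 could still fall, with Igf2 at -1.21. At that share, 0 risers among 62 had a one-sided binomial probability of 0.0828, with probe sets taken as independent, and many of the bright ones were ribosomal, so a ceiling and a true lack of change cannot be told apart for these enzymes.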

How the results depend on the processing

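Hybridization control scaling, single-array omissions and the estimated correlation without the replicate block were chosen after the data were seen. No called gene among the 79 changed sign, and no list was called in opposite directions, but the median of endoplasmic reticulum genes turned to -0.02 with hybridization control scaling while camera still called them higher (adjusted p = 0.00643), and the balance of changed probe sets turned from 1512 higher and 2019 lower to 2037 and 1503 with 75th percentile centring and to 1785 and 1714 with median centring. Counts of changed probe sets ran from 2833 to 4035 over scalings, filters, floor, pseudocount and trend, from 2472 to 3014 without 1 replicate pair and from 2461 to 3530 without 1 array, with 1107 at 2-fold or more; for genes the last ranges were 1905 to 2306 and 1896 to 2695, and for lists 8 to 10 in both. Leaving out samples lowered the counts of probe sets and genes, while lists rose to 10 without replicate 2 and without dexamethasone replicate 2; the cause of the other differences was not tested. Replicate numbers were set as a block because the design text speaks of pairs, but deviations of same-numbered arrays correlated at -0.10, 0.11 and 0.21, so the data do not show that numbers pair cultures, and control 1, control 2 and dexamethasone 1 correlated better with another number than with their own. With no replicate block, 3542 probe sets, 2710 genes and 9 lists were called, and no call of a list or of the 79 named genes changed. The 6 arrays allow 10 splits, too few for a share under 0.05. Only 1, the real split itself, gave as many changed probe sets (3531) and genes (2705). The highest other count was 0 for both, with up to 208 probe sets and 141 genes at an unadjusted limma p under 0.05. Regrouping the arrays put much of the treatment effect into the residual spread, which holds such counts down. The 0 is therefore no measure of chance. For lists 3 splits, the real one among them, gave as many (9, highest other 9). The others with 9 are the same fit, which contrasts control 1 with dexamethasone 1. All splits that part 1 pair contrast a single control with its treated partner and so hold the treatment effect. The 3 other splits that part all 3 pairs gave 8, 7 and 3 and keep part of that effect. The list counts are therefore no measure of chance either. Quantile normalization left 5 lists, losing endoplasmic reticulum (0.074), pancreatitis (0.37), ribosomal (0.019) and oxidative phosphorylation genes (0.11). Fry also left 5, losing the same 4 at medians of 0.23, 0.35, 0.30 and 0.26. The pancreatitis call was further lost with median centring (0.42), 75th percentile centring (0.47), no filter (0.28), a stricter filter (0.052) and a pseudocount (0.26), and its median ran from 0.30 to 0.56 without 1 pair and from 0.24 to 0.44 without 1 array, lost without replicate 1 and without dexamethasone replicate 1. Cholesterol and fatty acid genes became a call with no filter (-0.50); their median ran from -0.50 to -0.23 without 1 pair and from -0.52 to -0.30 without 1 array, with a call without replicate 2 or dexamethasone replicate 2. The estimated correlation, made from few residual degrees of freedom, left 0 lists (3 at an unadjusted p under 0.05), so medians of 2.28 (glucocorticoid), -2.30 (cell cycle), 1.20 (hepatocyte), 0.80 (digestive), 0.38 (stress response), 0.35 (pancreatitis), 0.30 (ribosomal), 0.26 (oxidative phosphorylation) and 0.23 (endoplasmic reticulum) were no longer called. Without the block it left 2, glucocorticoid and cell cycle genes. With the block, the estimates for glucocorticoid (-0.02) and hepatocyte genes (0.0076) lay below the preset 0.01, so correlation did not end those calls. Among named genes, quantile normalization ended 8 calls and added 2, hybridization control scaling likewise 8 and 2, and no intensity trend ended 7. Signal over background limits dim genes: bounds replace folds where a group lay at background. In simulated data over all probe sets tested, dim or not, 15.5% of 1.5-fold changes were recovered. Only 200 of 9520 probe sets were changed there, against 3531 called in the data. Adjustment was therefore stricter than in the data, and that share does not carry over to them.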

Other observations

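The genes in this part were chosen after their values were seen, and the list of amino acid breakdown enzymes and its test were added then.

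Outside the fixed lists, some single genes of lipid and carbohydrate use rose with dexamethasone; members of these pathways that did not rise were not counted and no such group was tested. Ehhadh, a peroxisomal enzyme of fatty acid oxidation, was not above background on any control array and was at least 12.2-fold higher with dexamethasone (limma adjusted p = 1.0e-05). Ech1, another enzyme of fatty acid oxidation, rose by 2.83 ± 0.14 on the log2 scale, and Cpt1a, which admits fatty acids to mitochondria, rose by 1.74 ± 0.15 on its brighter probe set and 1.26 on the other. Gpd1, which links glycolysis to glycerolipids, rose by 3.23 ± 0.14, the glycogen phosphorylase gene Pygl by 1.76 ± 0.18, and Klf15, a glucocorticoid-induced transcription factor, from 1058 ± 62 to 8146 ± 1226 (2.94 ± 0.12). Of lysosomal proteases, which were not tested as a group, Ctsl rose by 2.00 ± 0.11 and Ctsh by 2.87 ± 0.16. Amy1, an amylase with a separate probe set from Amy2a3, rose from 132.1 ± 44.5 to 1149 ± 410 (3.13 ± 0.18), with the paralogs open to cross-hybridization.

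Some signalling genes picked from the table moved in both directions. Ret, a receptor tyrosine kinase of neuroendocrine cells, fell by 3.40 ± 0.27 on its brightest probe set and fell by 3.62 ± 0.20 on another, and on the remaining probe set it was at background on all treated arrays, at least 14.5-fold lower. Gucy2c, the intestinal receptor for guanylin peptides, rose from 167.1 ± 89.6 to 2732 ± 968 (4.11 ± 0.16), while Guca2b, which encodes its ligand uroguanylin, fell from 4067 ± 204 to 627.9 ± 241.2 (-2.78 ± 0.23). Nppc, the C-type natriuretic peptide, fell by 3.42 ± 0.21 with 1 treated array above background, and Lgr5, a stem cell receptor, fell by 2.75 ± 0.16. The probe sets of Calca, whose transcript is spliced to calcitonin or to a neuropeptide, disagreed: the brightest fell from 5837 ± 431 to 2628 ± 620 (-1.18 ± 0.16), while the others rose by 1.05 ± 0.18 and 4.63 ± 0.14. Which transcript each probe set reads was not analysed here.

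Amino acid breakdown enzymes stood out among the largest rises, with 15 noticed first, such as Hpd, Tat, Gpt (4.09), Gnmt (3.58) and Agxt (3.36). As a hypothesis, the rise may extend across amino acid breakdown, and this was tested on 30 further measured enzymes of that list that had not been noticed; Arg1 among them had been seen. Limma called 19 of the 30 higher and 0 lower (0 also at an unadjusted p under 0.05), with a median log2 change of 0.79, and camera called them higher (p = 6.8e-10, adjusted p = 3.8e-09 beside the 16 lists, with the preset correlation; p = 0.0197, adjusted p = 0.112, with an estimated correlation, where the call is lost). Examples are Gstz1 (1.64 ± 0.12), Cbs (1.64 ± 0.17) and Gcdh (1.62 ± 0.12), and Got2 (0.29 ± 0.12), Dld and Shmt1 did not pass. The result fits a rise across this group with the preset correlation alone, and was found and tested on the same arrays.

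Several secreted protein genes varied together between cultures of the same group. Of 8 such genes (Ttr, Apoa1, Apoc3, Hp, C3, Serpina1, Pnliprp1 and Pnliprp2), 7 were highest among controls in control 2. Among controls, 6 were lowest or tied for lowest in control 3, and among treated arrays 8 were lowest in dexamethasone 3. Ttr had signals of 996, 1725 and 350 in controls 1 to 3 and 7129, 12962 and 1348 in dexamethasone 1 to 3. Dexamethasone 3 also had the highest Actb 3' to 5' ratio (1.69) and the highest background level (115.9) of the 6 arrays. Control 3 did not share these traits, with a ratio of 1.28 and the lowest background level (51.7). The genes were picked for this pattern, so neither it nor its relation to RNA quality or to replicate number was tested.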
